A study of Mus musculus with 6 samples.

How the data were processed

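Bulk RNA-seq of the pituitary gland of male mice was analysed in 6 libraries, 3 labelled RD and 3 labelled HFD. Per the labels, RNA was extracted from the gland with a column kit, polyadenylated RNA was selected with oligo-dT, and glands were taken after 16 h of fasting followed by 4 h of feeding. The labels do not spell out the diet abbreviations, give no batch or date, and do not state that the replicates of a group were separate animals, so p-values measure the spread between these libraries, which may in part be technical.

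The deposited table holds whole-number read counts per gene for the 6 libraries, with no normalization. Per the submitters' processing notes the genome build was mm10. The aligner, the counting tool, their versions and the annotation are not given in the sources used here. The table has 16736 rows, named by upper-case symbols in human style. Of these, 16199 (96.8%) matched a mouse symbol of GENCODE release M21 apart from case, and 16102 matched a single gene with coordinates on mm10 (GRCm38). Mouse genes without such a symbol are outside the table, so its column totals are totals of the listed rows and not the depth of the libraries. A symbol stood on 2 rows in 43 cases; such rows were tested one by one and kept out of the gene lists. Among counts from 1 to 10, between 64.0% and 67.0% were even, against 48.9% to 50.4% above 200 counts, as would follow if both mates of a read pair had been counted. Counting intervals would then be too narrow, so none are given and all errors come from the spread between libraries. The counts do not show whether strand was used in counting, so overlapping genes may share reads, and near-identical copies such as HSPA1A and HSPA1B cannot be separated with certainty. Although the labels name poly(A) selection, the non-polyadenylated RNAs RN7SK, RPPH1 and RMRP together held 1.11% to 1.28% of counts in the RD libraries and 1.28% to 1.43% in the HFD libraries.

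Totals of the listed rows were 16409233, 15702214 and 18111345 counts in RD replicates 1, 2 and 3, and 14185372, 14384933 and 14361032 counts in HFD replicates 1, 2 and 3. At these totals 3 counts correspond to between 0.166 and 0.211 CPM (counts scaled by the library total). No pair of libraries of a group was identical, and chi-square values per degree of freedom between replicates ranged from 4.57 to 22.1, so each library was counted as a separate sample.

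Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test (TMM factors, a filter with a minimum count of 10 and a minimum total of 15, an intercept and diet), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes past it are referred to as called. Changes are given as log2(HFD/RD) with the standard error, computed as the size of the log2 change divided by the square root of the F statistic, and levels as TMM-scaled CPM, mean ± SD with n = 3 per group. In total, 40 gene lists were fixed before the data were examined, and the 39 with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. For each list the called members are counted over all genes and after adjustment over the list alone. With a correlation estimated from the residuals, 0 lists passed at 0.05 (2 at an unadjusted p under it). By the directional test of fry, which asks whether the genes of a list move one way on balance, 2 passed. Values given for fry elsewhere are those of this test. The mixed test of fry, which takes changes in either direction, gave an adjusted p of 8.0e-05 for the hormone list and 0.0059 for the heat shock list. It gave 0.20 for the immediate early list.

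The rule for named genes was fixed before the data were examined. It takes the 12 largest rises and the 12 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, the 7 hormone genes, 12 genes of the unfolded protein response and thyroid hormone signalling, and up to 4 members of each list described, those with the smallest p-values. Genes named outside this rule are said to be so, and a few genes that the rule takes are not reported here. Gene symbols are given as in the deposited table and coordinates as in GENCODE M21.

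The alternatives tried were other scalings, other filters, DESeq2 1.42.0, limma-voom, other thresholds, a replicate block, each library left out in turn, and other list tests. Alternatives planned for a table of normalized values were not run, since the table holds counts. After the data were examined, halved counts, scaling from counts without the hormone genes, and the removal of each library's trend on GC content or transcript length (loess, span 0.4, centred in each library on the TMM level) were added. GC content and length were known for 13395 tested genes (96.6%).

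The fits were tested on simulated data drawn from the means, dispersions and totals of these libraries over 13873 genes, with 200 genes changed. In this simulated HFD versus RD comparison, edgeR recovered 10% of genes changed 1.25-fold, 70% at 1.5-fold, 82% at 2-fold and 90% at 3-fold, 50 genes each, and called 12 unchanged genes. Figures were drawn with matplotlib 3.10.9.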

Results

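The pituitary transcriptome of male mice labelled RD was compared with that of male mice labelled HFD, 3 libraries each, collected 4 h into refeeding after a 16 h fast. The title of the series places the comparison in the setting of obesity and asks about the unfolded protein response of the gland. Totals ranged from 14185372 to 18111345 counts over the listed genes, and 13873 genes were tested.

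Growth hormone transcripts (GH1) were lower and thyrotropin beta transcripts (TSHB) higher in HFD than in RD pituitaries, 12 of 15 heat shock genes were called lower, and 8 of 23 genes of fatty acid oxidation, ketogenesis and PPAR targets were called higher. These lists passed camera, but not with an estimated correlation (adjusted p = 0.87 for heat shock and adjusted p = 0.71 for fatty acid oxidation). By edgeR's quasi-likelihood test 1453 genes were called, 814 higher and 639 lower in HFD. Of these, 264 differed by at least 2-fold, 196 of them higher and 68 lower. The median size of the called changes was 1.47-fold. The groups did not overlap for 1451 of the called genes, and for 32.5% of all tested genes, where chance gives 10%. On the first principal component, which held 48.3% of the variance, the RD libraries lay between -36.2 and -9.68 and the HFD libraries between 19.1 and 24.4. RD replicate 3 lay farthest out, and without it 1414 genes were called. Measures of library composition also differed by group. The 12 listed mitochondrial genes held 0.754% to 0.819% of counts in the RD libraries and 0.907% to 0.976% in the HFD libraries. No row is named MT-CO1, so these are shares of part of the mitochondrial transcripts; the more abundant of the 2 rows named PTGS1, whose gene is uncertain, held 0.449% to 0.488% in RD and 0.522% to 0.547% in HFD. The non-polyadenylated RNA RN7SK held 0.804% to 0.911% and 0.932% to 1.01%. The groups did not overlap in any of these shares, where chance gives 10% for each. Of the other non-polyadenylated RNAs, RMRP did not overlap either (0.0465% to 0.0600% in RD and 0.0628% to 0.0728% in HFD). RPPH1 did overlap (0.257% to 0.309% in RD and 0.284% to 0.349% in HFD). All are shares of raw totals, and the TMM factors (0.956 to 0.996 in RD, 1.02 to 1.03 in HFD) would narrow such differences. The count of called genes fell to 890 without RD replicate 2, 701 without HFD replicate 1, 490 without HFD replicate 2 and 431 without HFD replicate 3. With library size as the only scaling, 72.5% of the calls were higher in HFD, against 56.0% with TMM.

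The largest rise was that of ANKFN1, from 0.453 ± 0.117 CPM in RD to 4.44 ± 1.58 CPM in HFD (SD, n = 3 each), a log2 change of 3.28 ± 0.38 (SE). SLC17A8, a vesicular glutamate transporter, rose 4.35-fold, from 9.47 ± 3.83 to 41.2 ± 3.90 CPM. GPR179, an orphan receptor known from retinal bipolar cells, rose 4.06-fold and was the most abundant of the 12, at 52.1 ± 12.7 CPM in RD and 212 ± 15.7 CPM in HFD. NR1H4, the bile acid receptor FXR, rose 4.43-fold from 1.69 ± 0.97 CPM. NR1H4 and SLC17A8 lie near each other on the minus strand of chromosome 10 of mm10 (89454234 to 89533585 and 89574020 to 89621253). Whether their rises are independent was not tested. PIPOX, a peroxisomal oxidase of pipecolic acid and sarcosine, rose 3.62-fold. The metabotropic glutamate receptor gene GRM2 rose 3.96-fold, the bicarbonate transporter gene SLC4A5 3.73-fold, the sperm axoneme gene SPAG16 3.85-fold and the immediate early gene EGR4 3.84-fold. SLC22A8, an organic anion transporter, rose 5.26-fold, CCKBR, the gastrin and cholecystokinin receptor, 3.96-fold, and C2CD4C 3.42-fold. Of these 12 calls, 9 held in each of the 6 fits with a library left out. SLC22A8 was not called without HFD replicate 3 (adjusted p = 0.0587), CCKBR without HFD replicate 2 or 3 (up to 0.0612), and C2CD4C without any of the HFD libraries (up to 0.0779). Without RD replicate 1 the log2 change of CCKBR was 2.62, against 1.98.

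Among the largest falls, PTPRQ, a receptor-type phosphatase, went from 11.6 ± 2.90 CPM in RD to 1.05 ± 0.30 CPM in HFD, a log2 change of -3.46 ± 0.28. TCERG1L fell from 39.7 ± 7.49 CPM in RD to 9.55 CPM in HFD. The transcriptional co-regulator gene CITED1 had a log2 change of -2.42 ± 0.41, and NIPAL1, a magnesium transporter gene, of -2.38 ± 0.36. VGF, which encodes a neuropeptide precursor of secretory granules, was at 31.2 ± 17.8 CPM in RD and 7.97 ± 1.01 CPM in HFD. The matrix metalloproteinase genes MMP7 and MMP20, which lie near each other on chromosome 9 of mm10 (7692090 to 7699585 and 7628231 to 7674979), had log2 changes of -3.54 ± 0.64 and -2.22 ± 0.50. The other falls of this rank were the heat shock genes HSPA1A, HSPA1B and HSPB1 and, with wide spread in RD, the phospholipase gene LIPH and the Nogo receptor gene RTN4R. LIPH stood at 28.2 CPM in RD replicate 3 against 2.94 and 3.97 CPM in RD replicates 1 and 2, RTN4R at 14.6 against 2.45 and 2.60 CPM, and MMP7 at 21.9 against 4.04 and 6.77 CPM. Without RD replicate 3 the log2 changes were -1.31 for LIPH, -1.50 for RTN4R, -2.53 for MMP7 and -1.60 for MMP20. Without HFD replicate 1 they were -3.69 for HSPA1B and -3.04 for CITED1, without HFD replicate 2 -3.48 for RTN4R, and without RD replicate 1 -2.06 for HSPA1B and -1.49 for HSPA1A. Of these 12 calls, 5 held with any library left out. The calls of MMP7, HSPA1A and HSPA1B were lost without HFD replicate 2 or 3, that of VGF without HFD replicate 3, those of MMP20 and LIPH without any HFD library, and that of RTN4R without RD replicate 3 or any HFD library, with adjusted p between 0.0513 and 0.179. By limma-voom MMP7, LIPH, RTN4R, HSPA1A and MMP20 were not called (adjusted p from 0.0603 to 0.202), nor was RTN4R by DESeq2 (0.0551), and halved counts ended the calls of LIPH and RTN4R (up to 0.0589).

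**Figure D1:**
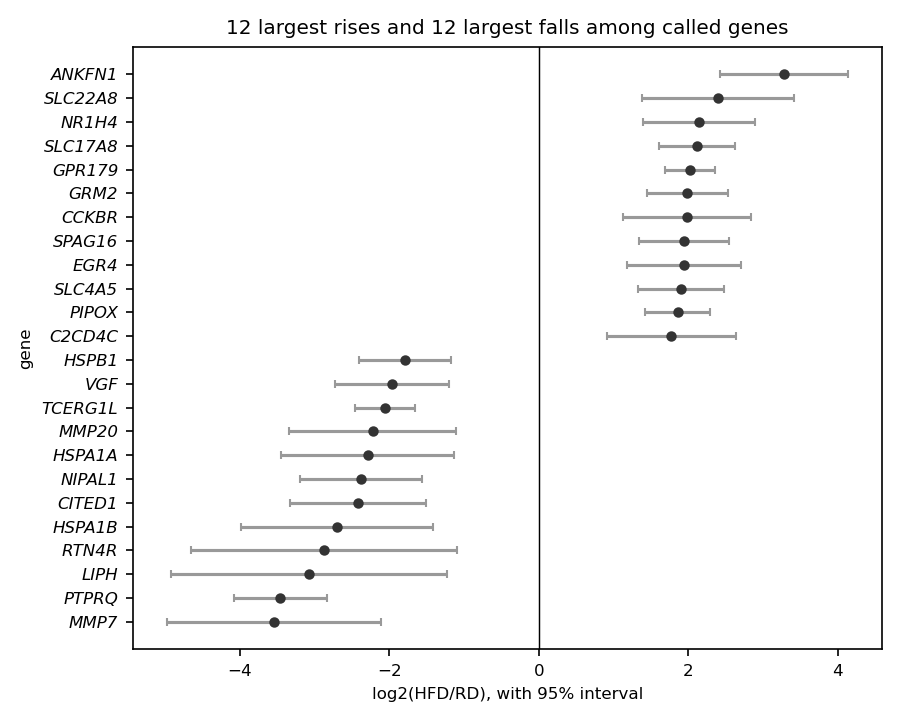
Log2(HFD/RD) on the horizontal axis for the 12 largest rises and 12 largest falls among called genes, 1 gene per row, with points for the edgeR estimate from 3 libraries per group and bars for the 95% interval. The estimates run from -3.54 for MMP7 to 3.28 for ANKFN1, and the widest bars belong to LIPH, RTN4R and MMP7.

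Of the 7 hormone subunit genes, 4 were lower and 2 higher in HFD. GH1 (mouse growth hormone, chromosome 11 of mm10, 106300271 to 106301865) fell from 67336 ± 7285 to 38005 ± 1472 CPM, a log2 change of -0.83 ± 0.07 (adjusted p = 0.00062). It took 6.57% ± 0.611 of counts in RD and 3.89% ± 0.136 in HFD (SD, n = 3 each). PRL, the prolactin gene (chromosome 13, 27057570 to 27065205), fell to 0.75 of its RD level, from 14482 ± 760 CPM. The gonadotropin beta subunit genes FSHB (-0.39 ± 0.07) and LHB (-0.36 ± 0.10) fell as well. TSHB, which encodes the beta subunit of thyrotropin (chromosome 3, 102775465 to 102782718), rose from 139 ± 38.9 to 287 ± 6.64 CPM, 2.06-fold (adjusted p = 0.0061). CGA, the alpha subunit shared by thyrotropin and the gonadotropins, rose 1.29-fold. POMC, the precursor of corticotropin, stood at 6837 ± 2261 CPM in RD and 10208 ± 4027 CPM in HFD and was not called (adjusted p = 0.23). The calls of GH1 and TSHB held with any library left out. LHB was not called in any of those 6 fits (adjusted p from 0.0517 to 0.115), nor with library size only (0.090) or upper-quartile scaling (0.072). PRL was not called without HFD replicate 2 (0.0556), and CGA and FSHB were not called without HFD replicate 2 or 3 (up to 0.0549).

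**Figure D2:**
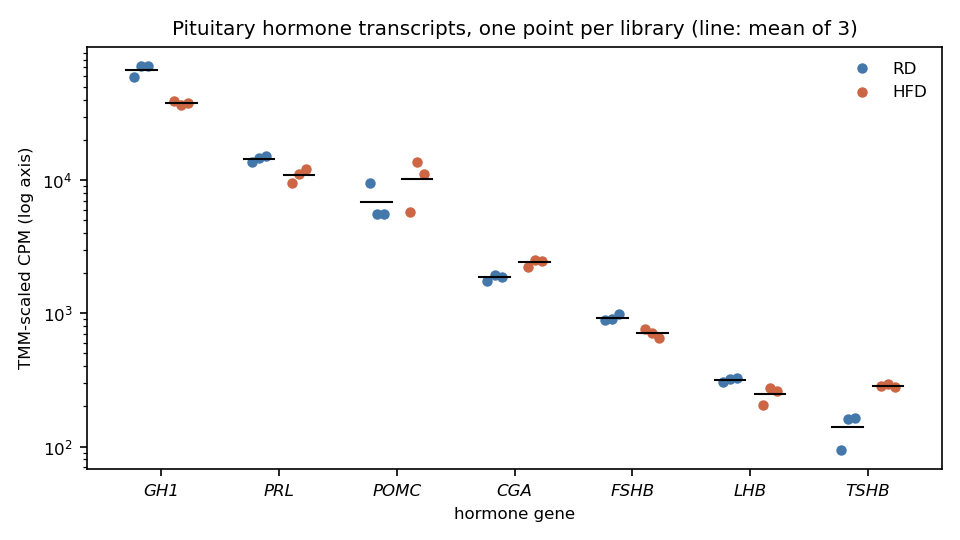
TMM-scaled CPM on a log axis for the 7 hormone genes, with 1 point per library in the RD and HFD groups and a line at the mean of 3. GH1 lies at 67336 CPM on average in RD and 38005 CPM in HFD, while TSHB lies at 139 and 287 CPM, and the POMC points of the groups overlap.

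Of 7 tested somatotroph markers 3 fell, namely GH1, POU1F1 (-0.84 ± 0.10), the transcription factor of the somatotroph, lactotroph and thyrotroph lineages, and PAPPA2 (-0.68 ± 0.13), a protease of IGF binding proteins, while IGFBP5 rose (0.26 ± 0.06). Adjusted over the list alone, 2 rose and 3 fell, and camera did not call the list (adjusted p = 0.17). Of 7 thyrotroph markers 4 rose, TSHB, CGA, the thyrotropin-releasing hormone receptor gene TRHR (0.53 ± 0.14) and GATA2 (0.56 ± 0.15), and 5 rose over the list alone (camera adjusted p = 0.013; adjusted p = 0.87 with an estimated correlation). That call was lost without HFD replicate 2 (adjusted p = 0.087) and with the hormone genes left out (0.13). Gonadotroph markers split, with GNRHR (-0.81 ± 0.14), FSHB and LHB lower and FOXP2 (0.68 ± 0.12), CGA and NR5A1 (0.49 ± 0.11) higher among 8 tested, and 4 higher and 3 lower over the list alone (adjusted p = 0.87). Of 7 lactotroph markers, ANGPT1 (1.27 ± 0.19) and NRG1 (0.25 ± 0.06) rose and PRL fell, and 2 rose and 2 fell over the list alone. Of 9 corticotroph and melanotroph markers CRHR1 alone was called, over all genes and over the list alone (0.36 ± 0.09). Among 16 lineage transcription factors 6 rose and 1 fell, over all genes as over the list alone (camera adjusted p = 0.11; 0.043 without RD replicate 1), with LHX3 (0.31 ± 0.08) and GATA2 beside NR5A1 on the higher side. The calls of GH1, POU1F1, TSHB, GNRHR and ANGPT1 held in each fit with a library left out, while those of PAPPA2 and FOXP2 were lost without HFD replicate 2 or 3 (adjusted p up to 0.069), those of IGFBP5 and GATA2 also without RD replicate 2 (up to 0.157), and those of NR5A1 and LHX3 without RD replicate 2 or any HFD library (up to 0.104). CRHR1 and NRG1 were not called without RD replicate 1, RD replicate 2 or any HFD library (up to 0.141), TRHR was called only without RD replicate 2 (otherwise up to 0.139), and removal of the GC content trend ended the call of LHX3 (0.0547).

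The list of thyroid hormone signalling and response held 3 higher and 1 lower gene among 16 tested, and 6 higher and 1 lower over the list alone. The receptor genes THRB and THRA moved apart, THRB from 308 ± 94.3 to 165 ± 3.44 CPM (-0.90 ± 0.17) and THRA upward (0.40 ± 0.08). DIO2, the deiodinase that activates thyroxine, had a log2 change of 0.25 ± 0.08 and was not called (adjusted p = 0.076). The list passed camera (adjusted p = 0.047; adjusted p = 0.87 with an estimated correlation) and fry (0.021). It did not pass camera in 5 of the 6 fits with a library left out, RD replicate 3 being the exception, with adjusted p up to 0.24, nor with the strict filter (0.0506) or without the hormone genes (0.12). THRB was not called without HFD replicate 2 or 3 (adjusted p up to 0.0632), THRA not without any HFD library (up to 0.0801), and DIO2 passed without RD replicate 3 (0.0197), with upper-quartile scaling (0.041), library size only (0.023) or the GC content trend removed (0.041).

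Among 22 ER chaperones and folding enzymes 6 fell and 16 did not pass the threshold, and over the list alone 9 fell and 1 rose. HSP90B1 (GRP94) went from 1016 ± 30.6 to 822 ± 23.3 CPM (-0.31 ± 0.05), and DNAJC3 (-0.34 ± 0.07), the disulfide isomerase gene PDIA6 (-0.33 ± 0.06) and DNAJB9 (-0.28 ± 0.07) fell likewise. HSPA5 (BiP), the main ER chaperone, was at 907 ± 114 CPM in RD and 744 ± 22.9 CPM in HFD and missed the threshold (adjusted p = 0.057). It passed in 3 of 19 other settings, by DESeq2 (adjusted p = 0.020), with no filter (0.047) and without RD replicate 1 (0.0249). In the remaining 16 it was not called (adjusted p up to 0.161). Over the 19 settings its log2 change ranged from -0.36 to -0.19. SDF2L1 had a log2 change of -0.07 ± 0.10. The list passed camera (adjusted p = 0.0027; adjusted p = 0.88 with an estimated correlation). Of 28 genes of ER-associated degradation, the translocon and signal peptidase, 4 fell, and 6 fell and 1 rose over the list alone. With library size as the only scaling 1 fell and 1 rose, 3 ER chaperones fell, and DNAJB9, SEC11A, SELENOS and SRPRA were not called (adjusted p from 0.0551 to 0.117). Upper-quartile scaling ended the calls of DNAJB9 (0.0537) and SRPRA (0.0684), and removal of the GC content trend that of DNAJB9 (0.0587). The 4 genes of the second list were SEC62 (-0.30 ± 0.07), SEC11A (-0.31 ± 0.07), SELENOS (-0.42 ± 0.10) and SRPRA (-0.22 ± 0.06), which serve protein import into the ER, signal peptide cleavage and retrotranslocation (camera adjusted p = 0.00092; adjusted p = 0.88 with an estimated correlation). HSP90B1 was not called without HFD replicate 3 (adjusted p = 0.0509), DNAJC3 not without HFD replicate 1 or 3 (up to 0.0716), PDIA6 not without HFD replicate 1 or 2 (up to 0.0584), and DNAJB9 was called only without RD replicate 1 (otherwise up to 0.133). The 4 genes of degradation and import were not called without any of the HFD libraries, nor SEC62, SEC11A and SRPRA without RD replicate 2, nor SEC11A and SELENOS without RD replicate 1 (adjusted p up to 0.161).

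Of 14 sensors and transcription factors of the unfolded protein response, 2 fell, and 2 fell and 1 rose over the list alone (camera adjusted p = 0.12). ERN1, which encodes the sensor IRE1 alpha, went from 228 ± 38.7 to 149 ± 13.6 CPM (-0.62 ± 0.12), and CREB3L1 had a log2 change of -1.48 ± 0.32. The transcription factor genes XBP1 (-0.30 ± 0.11), ATF6 (-0.10 ± 0.08), ATF4 (-0.19 ± 0.13) and DDIT3 (-0.27 ± 0.10) and the sensor gene EIF2AK3 (PERK, -0.04 ± 0.07) were not called. XBP1 was called without RD replicate 1 (adjusted p = 0.0247) but not in the remaining 18 of 19 other settings (adjusted p up to 0.27). Over these settings its log2 change ranged from -0.42 to -0.16. Splicing of XBP1 cannot be read from gene counts. In the list of 27 genes of the PERK and ATF4 amino acid response 2 rose and 3 fell, over all genes as over the list alone. SLC7A11, the cystine transporter, rose 1.62 ± 0.23 and ATF3 rose 1.34 ± 0.32, while asparagine synthetase ASNS (-0.65 ± 0.12) and VLDLR (-1.25 ± 0.25) fell, as did ALDH18A1 (-0.31 ± 0.07), chosen after its values were seen, and camera did not call the list (adjusted p = 0.33). Over the lists of ER chaperones, ER-associated degradation, sensors and the PERK and ATF4 response 17 genes were called. That number was 9 without RD replicate 2, 5 without HFD replicate 1, 5 without HFD replicate 2 and 2 without HFD replicate 3, where ERN1 was no longer called (adjusted p = 0.0695). ERN1 and VLDLR were not called without HFD replicate 2 or 3 (adjusted p up to 0.0816), CREB3L1 not without any HFD library (up to 0.0869), ASNS not without HFD replicate 3 (0.0569), and ATF3 not without RD replicate 2, HFD replicate 1 or HFD replicate 3 (up to 0.13).

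Of 15 heat shock response genes 12 fell (13 over the list alone) and 3 did not pass, and the list had the smallest camera p of all (adjusted p = 7.1e-09; adjusted p = 0.87 with an estimated correlation; fry adjusted p = 0.082). The median log2 change was -0.83. The HSP90 genes HSP90AA1 (-1.55 ± 0.17) and HSP90AB1 (-0.75 ± 0.08), the constitutive HSP70 gene HSPA8 (-1.15 ± 0.12) and the mitochondrial chaperonin gene HSPD1 (-0.83 ± 0.10) were among them. The small heat shock protein gene HSPB1 went from 89.1 ± 33.7 to 25.9 ± 7.86 CPM. The inducible HSP70 genes HSPA1A (44.4 ± 33.7 to 9.08 ± 4.82 CPM) and HSPA1B (55.9 ± 36.8 to 8.60 ± 7.39 CPM) are near-identical, so the split of reads between them is uncertain. Without RD replicate 3, 11 of the 15 genes were lower and the median was -0.70. Without HFD replicate 2 or HFD replicate 3, 7 were called, and HSPA1A and HSPA1B were not (adjusted p up to 0.116).

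**Figure D3:**
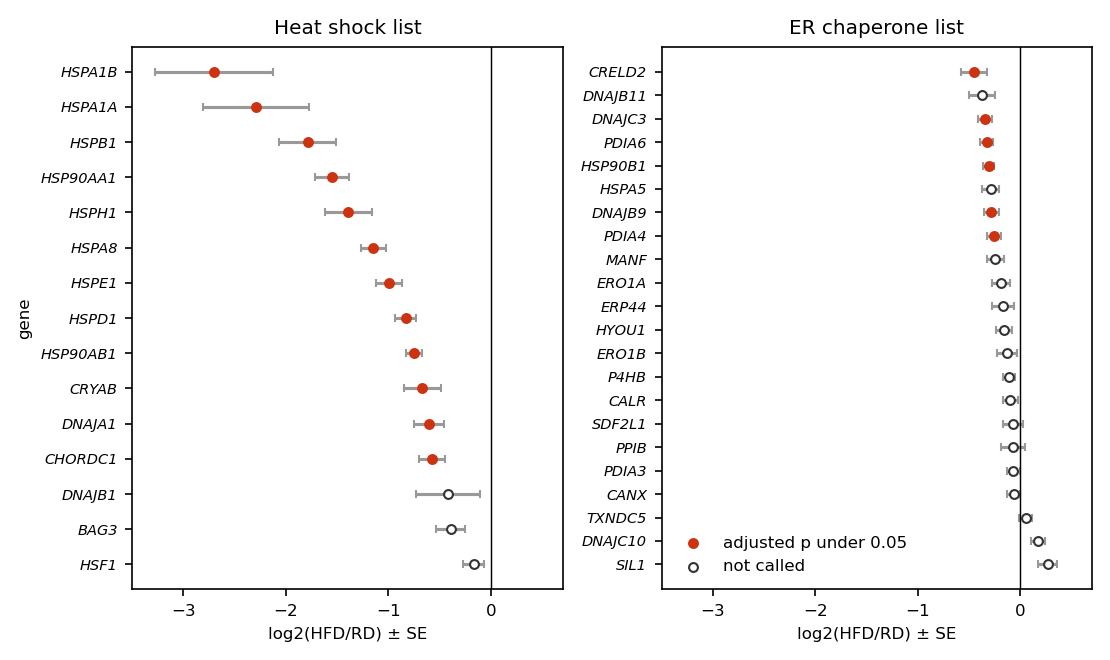
Log2(HFD/RD) with its SE for the 15 heat shock genes (left) and the 22 ER chaperones and folding enzymes (right), 1 gene per row, on the same horizontal scale; filled points passed the threshold and open points did not. In the left panel 12 genes are filled and the values reach -2.70, while in the right panel 6 genes are filled.

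Of 23 tested genes of fatty acid oxidation, ketogenesis and PPAR targets 8 rose and 15 did not pass the threshold, and 9 rose over the list alone (camera adjusted p = 0.0031; adjusted p = 0.71 with an estimated correlation; fry adjusted p = 0.0083). ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose 1.71 ± 0.23 on the log2 scale, the carnitine-acylcarnitine carrier gene SLC25A20 0.56 ± 0.10 and the mitochondrial carrier gene UCP2 0.36 ± 0.06. Of 15 fatty acid synthesis genes 3 fell, the elongase and desaturase genes ELOVL5 (-0.56 ± 0.09), FADS1 (-0.37 ± 0.08) and ELOVL6 (-0.36 ± 0.08), and PNPLA3 rose (0.86 ± 0.18), in the same numbers over the list alone, with no call by camera (adjusted p = 0.87). Of 22 cholesterol synthesis genes PMVK alone was called, over all genes and over the list alone (0.53 ± 0.10). The calls of SLC25A20 and PNPLA3 were lost without HFD replicate 2 or 3 (adjusted p up to 0.0767), where 3 of the 23 oxidation genes were called, and that of PMVK without HFD replicate 2 (0.0548). ELOVL6 was not called without RD replicate 2, HFD replicate 2 or HFD replicate 3 (adjusted p up to 0.108), and FADS1 not without RD replicate 2 or any HFD library (up to 0.0823).

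Of 17 interferon response genes 4 rose, namely GBP3 (1.16 ± 0.25), OAS2 (1.03 ± 0.23), USP18 (0.49 ± 0.13) and IFI27 (0.33 ± 0.09), and 9 rose over the list alone (camera adjusted p = 0.00016; adjusted p = 0.88 with an estimated correlation). Each of the 4 calls was lost without HFD replicate 1, 2 or 3, that of IFI27 also without RD replicate 2 or 3 and that of USP18 without any library (adjusted p up to 0.168). IFI27 was also not called with RLE scaling, with no filter, with the hormone genes left out or left out of the scaling, or with the GC content trend removed (adjusted p from 0.0508 to 0.0563). Of 20 immediate early genes 4 rose, EGR1 (1.57 ± 0.38), JUNB (1.46 ± 0.36), NR4A3 (1.40 ± 0.37) and ATF3, and 11 rose over the list alone (camera adjusted p = 0.00092; adjusted p = 0.92 with an estimated correlation). The camera call was lost without HFD replicate 1 (adjusted p = 0.059), the library with the highest mean of this list, and the groups overlapped in that mean, with RD replicate 1 (0.67) above HFD replicate 2 (0.31). EGR1 was not called without HFD replicate 1 or 3 (adjusted p up to 0.115), ATF3 also not without RD replicate 2 (up to 0.13), and JUNB and NR4A3 not without RD replicate 2, RD replicate 3, HFD replicate 1 or HFD replicate 3 (up to 0.122) or by DESeq2 (up to 0.0681).

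Some markers of other cell types moved with the diet. Of 9 oligodendrocyte and hypothalamic neuron markers, 3 rose, the myelin genes CNP (0.59 ± 0.11) and MAG (2.08 ± 0.44) among them, and 4 rose and 1 fell over the list alone (camera adjusted p = 0.23). Of 14 endothelial markers VWF rose (0.81 ± 0.15), of 13 fibroblast and pericyte markers COL1A2 fell (-0.69 ± 0.10) and CSPG4 rose (0.84 ± 0.19), and of 12 pituicyte markers VIM fell (-0.63 ± 0.15), in the same numbers over each list alone. Of 11 stem and folliculostellate markers 2 rose, ALDH1A2 (0.43 ± 0.09) among them, and LCN2 fell (-0.57 ± 0.12). Of 2 tested neutrophil markers MMP8 fell (-0.66 ± 0.13), and over each of these lists alone the numbers were the same. The call of COL1A2 held with any library left out, those of VWF and LCN2 were lost without HFD replicate 3 (adjusted p up to 0.0742), those of CNP, CSPG4 and MMP8 without HFD replicate 2 or 3 (up to 0.0965), and that of MAG also without RD replicate 2 (up to 0.0801). VIM was not called without RD replicate 1, RD replicate 2, HFD replicate 1 or HFD replicate 2 (adjusted p up to 0.103), and ALDH1A2 was called only without RD replicate 3 (otherwise up to 0.0867). In 6 lists no member was called by edgeR over all genes, those of oxidative phosphorylation, cytosolic ribosomal proteins, the cell cycle, macrophages, erythroid cells and skeletal muscle, and none of these lists passed camera. Of their 83 tested genes 6 had an unadjusted p under 0.05, 0 were called by DESeq2 or limma-voom, and 1 skeletal muscle marker was higher when adjusted over its list alone.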

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

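The block, the library-left-out fits, the scalings, filters and thresholds were planned; halved counts, scaling without the hormone genes and the removal of GC and length trends were chosen after seeing the data. No called gene among the 1453 changed sign in any of the 19 other fits. Since the groups did not overlap for 1451 of them, these fits could hardly reverse a sign, so this is no test of the calls. Among 170 named genes, 2093 of 2172 values in the 13 fits with all 6 libraries kept their side of the threshold, 58 lost a call and 21 gained one. In the 6 fits without a library, 790 of 1020 did, 222 lost a call and 8 gained one, where a group of 2 libraries also gives fewer degrees of freedom. Genes not called in the main fit also enter these values, and stay on their side by not being called. Of the 106 named genes called in the main fit, 33 were called in each of the 6 fits and 73 were not. With a library left out, called genes ranged from 431 to 1523, higher genes from 243 to 813, lower genes from 188 to 710, called hormone genes from 2 to 5, called genes of the unfolded protein response lists from 2 to 19 and lists past the threshold from 6 to 9. With library size only, 425 genes were lower (the TMM factors, higher in HFD, account for the direction of this shift). With an adjusted p under 0.1, 2343 genes were called, 1276 higher and 1067 lower. With at least 1.5-fold, 670 were called, 462 higher and 208 lower, among them 2 hormone genes and 6 of the unfolded protein response. With an estimated correlation 0 lists passed camera (2 at an unadjusted p under 0.05), and 2 lists passed fry. The estimated correlation was 0.75 for immediate early genes, 0.58 for heat shock, 0.46 for interferon and 0.44 for ER chaperones. It was 0.26 for ER-associated degradation and 0.16 for thyrotroph markers. The preset of 0.01 does not allow for members that vary together this much, so its camera p-values for these lists are likely too small. For fatty acid oxidation (-0.013) and thyroid hormone signalling (-0.039), the 2 lists that passed fry, the cause was not tested. DESeq2 called 1779 genes, leaving 270 without an adjusted p, and limma-voom 1406. Halved counts gave 1458.

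Over all genes the shared replicate numbers gave no sign of pairing: the deviations of same-numbered libraries correlated at -0.127, 0.0037 and -0.097. This does not exclude pairing in a part of the genes. The means of the immediate early list ran in the same order by number in both groups. They were 0.67, -0.62 and -0.05 in RD replicates 1, 2 and 3, and 1.52, 0.31 and 0.84 in HFD replicates 1, 2 and 3. With the replicate number as a block, 808 genes were called, 473 higher and 335 lower, with 9 genes of the unfolded protein response, and 785 of the 1453 genes were called again, while the immediate early list had a camera adjusted p of 8.3e-10, against 0.00092 without the block. The block brings a loss of residual degrees of freedom, which does not account for the lower camera p of the immediate early list. The block also takes spread shared by same-numbered libraries out of the residual, and the means of this list shared their order by number. With 3 libraries per group such an order can arise by chance. How much of the lower p comes from this was not tested. In the simulation, where 200 genes were changed, changes under 1.5-fold lay near the limit of 3 libraries per group. With more genes changed the adjusted threshold is less strict, so this limit need not hold for these data. The median size of the called changes was 1.47-fold.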

Other observations

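The tests of the hormone share in the totals, of the somatotroph share, of POU1F1 and of the imprinted genes were chosen after the result was seen, and the removal of GC and length trends after seeing the data. Several clock genes differed between the groups. All glands were taken at the same point of refeeding, but this does not show that the groups were taken at the same time of day, which was not tested. Of 18 tested, 5 fell and 1 rose, over all genes as over the list alone, without a call by camera (adjusted p = 0.66). PER2 fell (-1.04 ± 0.23), as did NR1D2 (-0.34 ± 0.06), while PER1, which glucocorticoids also induce, rose (0.79 ± 0.16). CRY1 (-1.04 ± 0.28) and TEF (-0.25 ± 0.07), chosen after their values were seen, fell too. Of 15 glucocorticoid response genes 3 rose, ERRFI1 (1.04 ± 0.12), PER1 and SGK1 (0.57 ± 0.14), and 2 fell, LCN2 and ZBTB16 (-0.56 ± 0.15), the latter chosen after its values were seen, and over the list alone 4 rose and 3 fell. PER2 and NR1D2 were not called without HFD replicate 2 or HFD replicate 3 (adjusted p up to 0.102), PER1 not without HFD replicate 1 or HFD replicate 3 (up to 0.0701), and SGK1 not without any HFD library (up to 0.105).

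Of 20 insulin, IGF and FOXO signalling genes 4 rose, TXNIP (0.66 ± 0.08), a glucose-responsive inhibitor of thioredoxin, IGF1 (1.10 ± 0.22), CISH (0.44 ± 0.09) and IGFBP5, with 5 higher and 1 lower over the list alone; the list's median was -0.05 and its mean 0.08, and the median and mean also differed in sign in the hormone, NRF2, secretory granule, cholesterol synthesis, lactotroph and skeletal muscle lists, which camera did not call. Of 18 NRF2 targets, NQO1 (1.07 ± 0.14) and SLC7A11 rose, with the same count over the list alone. Of 20 genes of the list of receptors of releasing and inhibitory factors 3 rose, CRHR1 and TRHR among them, and GNRHR fell, with 3 higher and 3 lower over the list alone, and of 20 secretory granule genes VGF, RAB27A (-0.26 ± 0.06) and PAM (-0.25 ± 0.06) fell, with 2 higher and 3 lower over the list alone. LAMP2 fell (-0.27 ± 0.06) as the single called gene of 20 autophagy and lysosome genes (camera adjusted p = 0.13; 0.0183 without RD replicate 3), CD74 rose (0.37 ± 0.09) as that of 8 antigen presentation genes, in the same numbers over each list alone, and of 13 inflammatory genes NOS2 rose (1.24 ± 0.32) and LCN2 fell, with 2 higher and 1 lower over the list alone. The calls of TXNIP, NQO1, SLC7A11 and GNRHR held with any library left out, those of IGF1 and CISH were lost without HFD replicate 1 or 3 (adjusted p up to 0.0691), those of VGF and LCN2 without HFD replicate 3 (up to 0.0742), and that of CD74 without any HFD library (0.11). RAB27A and LAMP2 were not called without RD replicate 2 or any HFD library (adjusted p up to 0.0977), NOS2 was called only without RD replicate 3 (otherwise up to 0.137) and PAM only without RD replicate 1 (otherwise up to 0.154), and library size as the only scaling ended the calls of RAB27A, PAM and LAMP2 (up to 0.0861) and upper-quartile scaling that of PAM (0.0566). A list of imprinted genes chosen after NNAT, PEG10 and BLCAP were seen among the genes with the smallest p held 2 higher genes, NNAT (0.71 ± 0.06) and BLCAP (0.55 ± 0.06), and 4 lower, PEG10 (-1.46 ± 0.13), IGF2R, ASB4 and PLAGL1, among 24, all named after their values were seen, with a median log2 change of 0.00 and a mean of -0.14, and was not called by camera. A pair of rows both named PTGS1 held very different counts, 73998 to 81283 and 145 to 256.

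The lower heat shock transcripts were first set against RD replicate 3, the library farthest from the others. Without it the median of the list was -0.70 and 11 genes were still called lower, so this library alone does not account for them. A held-out list of 20 other targets of the heat shock factor HSF1, fixed before its values were seen, had a median log2 change of -0.25 with 9 genes lower and 1 higher (UBB, named after its values were seen), 13 and 1 over the list alone (camera p = 3.4e-06; p = 0.13 with an estimated correlation), so lower HSF1 activity in HFD glands is a candidate explanation. Cooler HFD glands before collection stay open: RBM3, a cold-inducible RNA, was higher (0.34 ± 0.07, adjusted p = 0.017), which met the condition set for it, but its 95% interval (0.18 to 0.50) also lay below the bound of 0.72 set against it, as 0.5 of the change of CIRBP (1.45 ± 0.12, chosen after its values were seen). That bound was wrong as set, since it rules out values of RBM3 that the explanation itself predicts, such as this called rise, and since it was scaled to a gene picked for its large change, so the test does not decide.

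For the hormone genes, the largest log2 shift of all other genes that the hormone shares of the totals can give, from the highest RD to the lowest HFD share, was 0.0528. The 95% intervals of the 6 called hormone genes all lay farther from 0 (nearest for LHB, with a bound of -0.14), which argues against scaling by these shares as the cause. A lower share of somatotrophs as the whole cause would raise the transcripts of the other cell types alike, yet FSHB fell (-0.39) while TSHB rose. Lower POU1F1 as the whole cause would lower TSHB, a gene it activates, and TSHB rose (1.04). Both points use the hormone values that are to be explained, so they are no independent tests. They leave open that somatotroph share or POU1F1 had a part in the pattern. A change in thyrotroph number or activity and an effect of the diet on each cell type stay open, as untested.

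For the 1453 called genes, 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05; the 1 real split gave 1453 genes by edgeR and the highest of the others 0 (at most 814 at an unadjusted p under 0.05, against 3679). After removal of GC content trends 92.4% of the 1412 called genes with a value were called again with the same sign, and after removal of transcript length trends 99.3%, which argues against either trend as the whole cause. Without removal, the direction of the calls differed with GC content. In the lowest of 5 GC bins 121 genes were higher and 136 lower, with a median log2 change of -0.036 over the bin. In the highest bin 196 were higher and 81 lower, with a median of 0.038. Collection, RNA quality or library batches that follow the diet stay open, since the labels give none. In raw totals, before TMM scaling, the shares of mitochondrial genes and RN7SK were higher in each HFD library than in any RD library. The share of RPPH1, another non-polyadenylated RNA, overlapped between the groups.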
